A study of Schizosaccharomyces pombe with 87 samples.

How the data were processed

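The study labels describe chromatin immunoprecipitation and sequencing for H3K9me2 and H3K9me3 in fission yeast grown at 32 °C to log phase. Per the labels' protocols, cells were fixed in 1% formaldehyde for 15 minutes and libraries were made from 1 ng of DNA. Trimmomatic and BWA are named in the submitters' processing notes. Their versions, the settings and the genome build the authors used are not given in the sources used here. Samples were grouped by genotype, antibody, fraction and strain set from their titles, and replicate numbers were taken from the titles. The treatment label of 1 endogenous input differs from its title, and the title was followed. Endogenous inputs that are labelled with both antibodies were placed under the antibody that their title names first.

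The 2 deposited files used here are genome annotations, and their start and end fields are positions in bp that belong to no sample. The all-chromosomes annotation credits its records to PomBase, per the file headers and source fields. The tetarr6 annotation was exported from Geneious 7.1.5, per the file headers, and names its chromosome III as modified. No file used here gives counts, signal or peaks, so the depth of the libraries is unknown here. The planned comparison of immunoprecipitated over input signal had no values to run on, and no test, p-value or interval is given. Because every reported value is an annotated position or a count of annotated features, its precision depends on the annotation and not on sequencing depth.

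Genes were matched by systematic identifier, ignoring case. A gene was taken as protein-coding where it had a messenger RNA record in the all-chromosomes annotation or a coding sequence record in the tetarr6 annotation, since the former gives a coding sequence record to all 7196 of its long and small non-coding transcripts as well. The offset of a gene is its start in one annotation minus its start in another. An offset was kept where at least 20 genes of a chromosome shared it, and runs of fewer than 3 neighbouring genes were dropped. The bound of 20 genes was chosen after the data were examined. The comparison with RefSeq (ASM294v3) was also added then, to tell which annotation had been edited. RefSeq may not be the build behind either file. Its chromosomes I and II have the lengths that the tetarr6 annotation gives, and the replaced bases in that annotation matched its chromosome III exactly, so positions were compared with it, and none was converted. Windows of 20 kb were used for neighbouring genes, with 10 and 50 kb as alternatives. The tet operator was searched on both strands, exactly and with 1 mismatch. The operator sequence comes from general knowledge and from no file.

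The offset procedure was tested on simulated data. In 60 simulated edits of RefSeq with unchanged gene lengths, the offset was recovered exactly in 60. In 60 edits of smaller gene sets with many starts and ends moved at random, the offset was recovered exactly in 60. The simulated position of an edit was not compared with the block borders, so the border genes were not tested in this way. These simulations hold 1 edit per chromosome, whereas the tetarr6 annotation has a pair of edits on chromosome III. No simulated edit lay as near a chromosome end as ura4, where the tetarr6 block before the edit holds 54 genes.

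The genes named in the text are those of lists fixed before the data were examined: the genotype genes, HP1 and chromodomain proteins, the Clr4 complex, RNA interference, SHREC and deacetylases, the Mst2 and Set1 complexes, anti-silencing factors, reporter genes, heterochromatin islands, subtelomeric genes and euchromatic reference genes. The rule adds the nearest gene on either side of an inserted feature and genes within 20 kb of it that stand in 1 annotation only. Of the latter, 0 genes of the tetarr6 annotation were found near Tetarr-ade6, and 15 of the all-chromosomes annotation near the shortened ura4 locus, of which the closest is named. Under the separate sequence name 2 were found near 9xtetoura4, and 6 genes of the tetarr6 annotation near the edited interval of chromosome II. Both the shortened ura4 locus and that interval were searched in place of an inserted record. The values of 1 listed gene are not reported here, and it is included only in the counts. Other genes named as block borders, as RefSeq genes of the mating-type interval or as neighbours within 20 kb (rhp7 and rhp16) were chosen after their positions were seen. Scripts ran in Python 3.11.15, with matplotlib 3.10.9 for the plots.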

Results

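The series profiled the heterochromatin marks H3K9me2 and H3K9me3, histone H3 carrying 2 or 3 methyl groups on lysine 9, by chromatin immunoprecipitation and sequencing in fission yeast, Schizosaccharomyces pombe. The labels describe 87 libraries, 48 from immunoprecipitated DNA and 39 from input DNA. They fall into a strain set labelled ectopic, with 56 libraries, and a strain set labelled endogenous, with 31. The ectopic set holds 7 genotypes: wild type, swi6Δ, swi6Δ mst2Δ, swi6Δ set1Δ, swi6Δ mst2Δ set1Δ, mst2Δ set1Δ and clr4Δ. The endogenous set holds 5 of these and lacks mst2Δ set1Δ and clr4Δ. Swi6 is an HP1 protein that binds methylated H3K9, Clr4 is the H3K9 methyltransferase, Mst2 is a histone acetyltransferase and Set1 is the H3K4 methyltransferase. In the ectopic set each of the 28 combinations of genotype, mark and fraction has 2 libraries. In the endogenous set each genotype has 2 immunoprecipitated libraries per mark. It has 11 inputs, of which 8 are labelled with both antibodies, so some input libraries were shared between the marks. Shared inputs were filed under the antibody that the title names first. This filing gives 16 groups, with 1 library in the wild-type H3K9me3 input group and no H3K9me3 input group for the 4 mutants. An absent group follows from the filing and does not show that a mutant lacked an input for H3K9me3. The wild type and swi6Δ each have an input whose title names both marks, filed under H3K9me2.

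The comparisons that the genotypes imply, namely H3K9me2 and H3K9me3 in each mutant against wild type within a strain set, were not analysed here, because the files used here hold no value of any library. Both files are genome annotations. Their score field is empty in every record, so 0 of 58359 records of the one and 0 of 40352 records of the other carry a measurement. No enrichment, depth or difference between genotypes is therefore given, and no test was run. What the files do describe is the pair of edited genomes, with the reporter constructs they carry, and the positions of the heterochromatin genes and regions in each. The values that follow are positions and counts of annotated features, with no replicates and no sampling error. No label used here states which annotation belongs to which strain set.

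The first annotation, called the all-chromosomes annotation here, lists 12633 genes, of which 5113 have a messenger RNA record. The other, called the tetarr6 annotation here, lists 6951 genes, of which 5120 have a coding sequence. By systematic identifier 6779 genes stand in both, 5095 of them protein-coding in both. The 5854 genes found only in the all-chromosomes annotation are mostly non-coding: 5780 are SPNCRNA genes and 11 are protein-coding. The 172 genes found only in the tetarr6 annotation include 138 SPNCRNA genes and 21 protein-coding genes. Beside the RefSeq annotation of the ASM294v3 assembly, 12594 genes of the all-chromosomes annotation and 6780 of the tetarr6 annotation have a counterpart. Gene lengths equal those in RefSeq for 99.9% of the shared genes in the former and for 28.3% in the latter.

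The positions of shared genes showed where the coordinates of the 2 annotations step apart. On chromosome I shared genes kept 1 offset of 0 bp between the annotations. On chromosome II the tetarr6 positions equalled those of the all-chromosomes annotation up to the mating-type region and differed by -6539 bp from SPNCRNA.1489 to the end. On chromosome III the difference was 0 bp up to tam14, 3041 bp from new25 to bub1 and 1213 bp from vtc4 to the end. These offsets were exact for 4351 of the 6779 shared genes, or 64.2%, and 1574 of those 4351 lay at different positions in the 2 annotations. The starts of the remaining shared genes differed from the offset of their block.

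**Figure D1:**
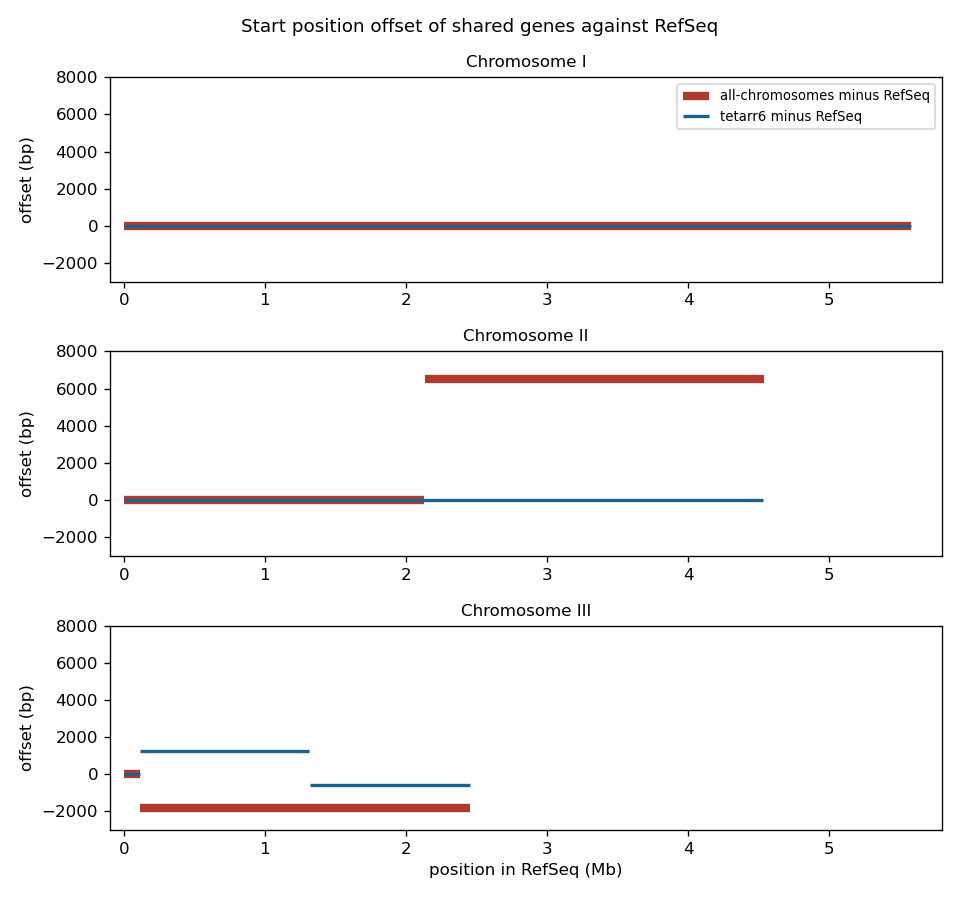
Offset of gene starts against RefSeq (vertical axis, bp) along each chromosome (horizontal axis, RefSeq position in Mb), for the all-chromosomes annotation (thick line) and the tetarr6 annotation (thin line); each line spans a block of genes with 1 offset. The all-chromosomes annotation steps to 6539 bp on chromosome II and to -1807 bp on chromosome III, and the tetarr6 annotation steps to 1234 bp and then to -594 bp on chromosome III.

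Each step was assigned to an annotation by comparison with RefSeq. The tetarr6 annotation follows RefSeq on chromosomes I and II, where its sequences are 5579133 and 4539804 bp long in both. Its chromosome III is 2452289 bp long, against 2452883 bp in RefSeq, a difference of -594 bp. That difference is the sum of a gain of 1234 bp at ura4 and a change of -1828 bp at ade6. The all-chromosomes annotation differs from RefSeq by 6539 bp from SPNCRNA.1489 to the right end of chromosome II, over 2461 genes. On chromosome III it differs by -1807 bp from new25 to the right end, over 2258 genes. In that annotation 157 records carry a position in their own identifier. Of these, 117 start at that position, 18 on chromosome II start 6539 bp from it and 22 on chromosome III start -1807 bp from it.

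At the ura4 locus, which encodes an enzyme of uracil synthesis used as a selectable reporter, both annotations lack the ura4 gene. In RefSeq ura4 (SPCC330.05c) lies on chromosome III at 115589 to 116625, minus strand, between tam14 and new25. The tetarr6 annotation holds in its place a record named Tetarr-ade6 at 115325 to 118393, 3069 bp long, on the minus strand. An editing record in the same annotation keeps the bases that were replaced. This segment of 1835 bp matched RefSeq chromosome III exactly and once, at 115325 to 117159, and contains the whole of ura4. The gain of 3069 over 1835 bp is 1234 bp, the offset of the genes that follow. Tetarr-ade6 begins 68 bp after tam14 and ends 418 bp before new25. Its own bases were not used here, so the number of operators in it is not given. The operator was searched only in sequence without the construct, which cannot bear on that number. The replaced segment has 0 copies of the 19 bp tet operator TCCCTATCAGTGATAGAGA, and so has RefSeq on chromosomes I, II and III.

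**Figure D2:**
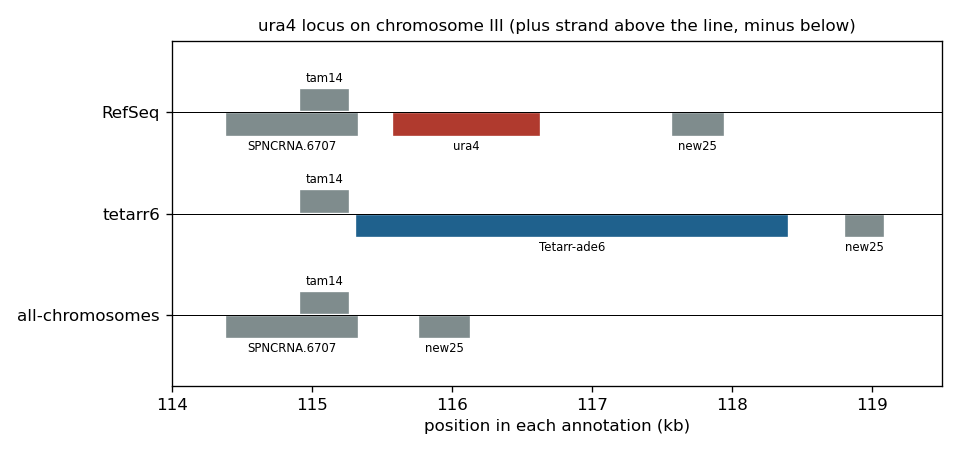
Genes at the ura4 locus of chromosome III in RefSeq, the tetarr6 annotation and the all-chromosomes annotation, with the position in each annotation in kb on the horizontal axis; bars above a line are on the plus strand and bars below it on the minus strand. A record of 3069 bp replaces ura4 in the tetarr6 annotation, and tam14 and new25 stand 514 bp apart with no ura4 in the all-chromosomes annotation.

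In the all-chromosomes annotation the same locus was shortened without a replacement record. SPNCRNA.6707 ends at 115323 and new25 starts at 115771, which leaves 447 bp between them against 2254 bp in RefSeq. The net change of -1807 bp is 28 bp smaller in size than the 1835 bp segment replaced in the tetarr6 annotation.

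The ade6 gene, an adenine synthesis gene whose loss colours colonies red, is kept in the all-chromosomes annotation and absent from its own locus in the tetarr6 annotation. In RefSeq ade6 (SPCC1322.13) lies on chromosome III at 1316281 to 1318035, 1755 bp long, on the plus strand. In the all-chromosomes annotation it lies at 1314474 to 1316228. In the tetarr6 annotation no ade6 record stands between bub1, which ends at 1317239, and vtc4, which starts at 1317781. The space between these flanking genes is 541 bp there and 2377 bp in RefSeq, where bub1 is 8 bp shorter.

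On chromosome II the all-chromosomes annotation has no gene lying wholly within the mating-type interval between SPNCRNA.5505, which ends at 2129020, and the remainder of SPNCRNA.391, at 2143661 to 2143663. The latter is a remnant of 3 bp of a gene of 83 bp in RefSeq. The interval spans 14640 bp up to the remnant, against 8101 bp up to the same base in RefSeq. The 6 RefSeq genes within it have no record there under their own identifiers: mat3-Mc, mat3-Mi and the non-coding SPNCRNA.389, SPNCRNA.390, SPNCRNA.5506 and SPNCRNA.5507. The first 4 of these are present at their RefSeq positions in the tetarr6 annotation. The all-chromosomes annotation instead lists 3 gene records under a separate sequence name for the mating-type region, all on the minus strand. These are mat2-Pc (SPMTR.01) at 2132562 to 2132961, 9xtetoura4 at 2135068 to 2136948 and mat3 at 2139388 to 2139933. The 9xtetoura4 record is 1881 bp long, 844 bp more than the ura4 gene in RefSeq. It is shorter than the 6539 bp step, so this record alone cannot account for the step. No RefSeq gene on chromosomes I to III has the identifier of mat2-Pc. How much of the step is inserted construct, and how much is other sequence that RefSeq lacks, was not tested. The record lies 2106 bp from mat2-Pc and 2439 bp from mat3, the 2 other genes under that name. The tetarr6 annotation has no gene with either of their identifiers. The mat3 record is 546 bp long, as is mat3-Mc in RefSeq, and its start is 6539 bp above that of mat3-Mc. It may therefore be mat3-Mc under another identifier, though it is written on the other strand. Within 20 kb of the edited interval the tetarr6 annotation has 6 genes whose identifiers the all-chromosomes annotation lacks. They are mat3-Mc, mat3-Mi, SPNCRNA.389, SPNCRNA.390, SPNCRNA.514 and SPNCRNA.1486. Of these, SPNCRNA.514 and SPNCRNA.1486 lie outside the interval and are missing from RefSeq as well.

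**Figure D3:**
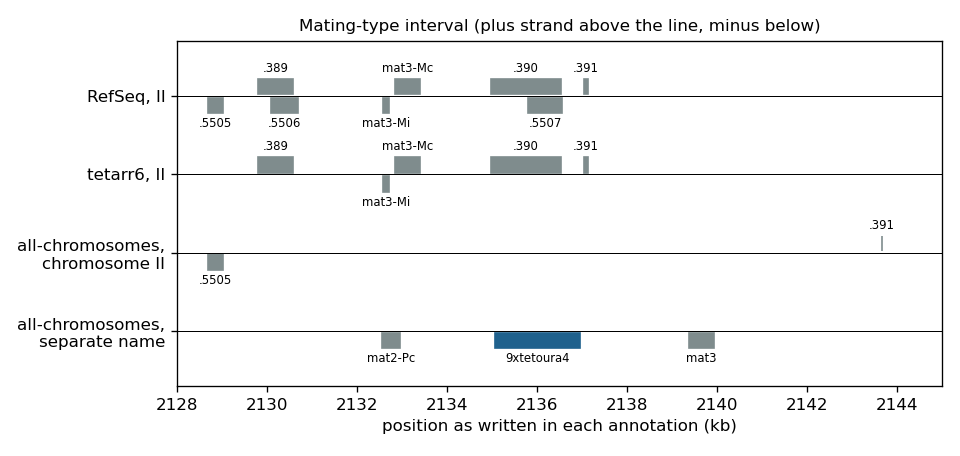
Records of the mating-type interval with their positions as written (kb, horizontal axis) in RefSeq, the tetarr6 annotation and the all-chromosomes annotation, the last split by sequence name; labels that begin with a point are SPNCRNA genes. The all-chromosomes annotation leaves chromosome II empty between 2129020 and the remnant at 2143661, and lists 3 records under the separate name.

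Of the 52 genes in the lists fixed before the data were examined, 51 were in the all-chromosomes annotation and 50 in the tetarr6 annotation. The exceptions were ura4, in neither, and ade6. Among the 50 genes in both, 30 lay in a block with equal positions in the 2 annotations and 20 in a block with shifted positions. All 50 had a start or an end in the tetarr6 annotation at the offset of their block against RefSeq. The shifts given for listed genes are the offsets of their blocks between the annotations, and the start of a single gene can differ by another amount where it was drawn differently. For example, adh1 starts at 1589485 in the all-chromosomes annotation and at 1588833 in the tetarr6 annotation, while its ends, 1591082 and 1592295, follow the block offset.

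All 4 genotype genes are annotated in both genomes, so the deletions in the strains are not drawn into either annotation. The swi6 gene lies on chromosome I at 1702406 to 1704098 in the all-chromosomes annotation, and mst2 on chromosome I at 2363499 to 2366934. The clr4 gene lies on chromosome II at 453996 to 458410. These 3 genes had offset 0 between the annotations. The set1 gene, on chromosome III, starts at 410486 in the all-chromosomes annotation and at 413527 in the tetarr6 annotation, a difference of 3041 bp.

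Among the HP1 and chromodomain genes, 1 of 3 was shifted: chp2, the other HP1 gene, ends at 4357783 in the all-chromosomes annotation and at 4351244 in the tetarr6 annotation, a difference of -6539 bp. Among the 5 genes of the Clr4 complex, 2 were shifted, raf2 by 3041 bp and rik1 by 1213 bp. Among the 10 RNA interference genes 6 were shifted. The blocks of the Argonaute gene ago1 and of ers1 were shifted by 3041 bp, those of the Dicer gene dcr1, hrr1 and cid12 by 1213 bp, and that of stc1 by -6539 bp. Of the 5 SHREC and deacetylase genes, clr1 and sir2 were shifted by -6539 bp and clr2, clr3 and mit1 were not. In the Mst2 complex 2 of 7 genes, nto1 and ptf2, were shifted by -6539 bp. In the Set1 complex 3 of 8 were shifted, set1 by 3041 bp, ash2 by -6539 bp and sdc1 by 1213 bp. Of 4 anti-silencing genes, epe1 was shifted by 1213 bp and leo1 by -6539 bp. The heterochromatin island genes mei4, ssm4 and mcp7 had equal block positions. Of the subtelomeric genes tlh1 was not shifted and tlh2 was, by -6539 bp. Of the reference genes act1 and leu1 lay in blocks that were not shifted, and adh1 in a block shifted by 1213 bp. A shift depends only on where a gene lies relative to the steps, so these counts describe no trait of the groups. Among all shared genes at a block offset 36.2% were shifted. The share was 0.0% on chromosome I, 51.6% on chromosome II and 93.5% on chromosome III.

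Around Tetarr-ade6, 29 genes of the tetarr6 annotation, 19 of them protein-coding, lay within 20 kb. The nearest were tam14 and new25, and the genes within that distance include the DNA repair genes rhp7 and rhp16. None of these genes was missing from the all-chromosomes annotation. Within 20 kb of the interval between tam14 and new25, the all-chromosomes annotation had 15 genes that the tetarr6 annotation lacks, 0 of them protein-coding. The closest of the 15 was SPNCRNA.6707, which overlaps tam14 on the other strand. Over the whole all-chromosomes annotation 5854 of 12633 genes are lacking in the tetarr6 annotation, 11 of them protein-coding, so such genes are not particular to this locus.

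The centromeres, which carry constitutive heterochromatin, each have a record in the all-chromosomes annotation; these are annotated spans, and their completeness was not tested. The centromere of chromosome I spans 3753687 to 3789421, that of chromosome II 1602418 to 1644747 and that of chromosome III 1069097 to 1135196. The lengths of these records are 35735, 42330 and 66100 bp. The dg and dh outer repeats, which are transcribed and feed the RNA interference pathway, number 4, 6 and 17 on chromosomes I, II and III. They cover 41.8%, 49.1% and 61.5% of the 3 records. The tetarr6 annotation has a repeat region at the offset interval of all 4, all 6 and all 17 of them. The repeats of chromosome III lie 3041 bp further right there. Within the centromeres the all-chromosomes annotation lists 28, 48 and 60 genes, none of them protein-coding. Of these 6, 9 and 12 are transfer RNA genes.

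At the chromosome ends, taken as the first position and the last annotated feature, protein-coding genes were counted within 20 kb in the all-chromosomes annotation. There are 4 among 22 genes at the left end of chromosome I and 7 of 17 at its right end. There are 8 of 19 at the left end of chromosome II and 1 of 26 at its right end. On chromosome III there are 0 of 18 at the left end and 2 of 14 at the right end. These are ends of the annotated sequence, and whether they reach the telomeres was not tested. The tlh1 record starts at position 1 of chromosome I. Chromosome III starts with SPRRNA.42 and ends with SPRRNA.45, so its counts should not be read as subtelomeric gene content.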

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

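The H3K9me2 and H3K9me3 alternatives planned before the data were examined (another pseudocount, leaving out each replicate, and a replicate block) were not run, since no file used here holds values per library. No paired analysis was possible because the files used here carry no value of any sample. Counting records with the same chromosome, type, start, end and strand once, whatever their identifiers, left 58288 and 40341 records. Matching genes by name lowered the shared genes from 6779 to 2981, by construction, since many genes have no name; protein-coding genes alone gave 5095. The 3 offsets between the annotations were found again, and no other, with ends in place of starts and with genes of equal length only. The same held for the 2 offsets of each annotation against RefSeq. Bounds of 10 and 50 genes per offset, chosen after seeing the data, also gave the same offsets. Genes of equal length were fewer: 323 in place of 799 at -6539 bp, 160 in place of 375 at 3041 bp and 188 in place of 400 at 1213 bp. The genes near Tetarr-ade6 numbered 19 within 10 kb and 67 within 50 kb, against 29 within 20 kb. With 9xtetoura4 placed on chromosome II, a placement chosen after seeing the data, 32 genes lay within 20 kb, 13 within 10 kb and 96 within 50 kb. The operator search gave 0 copies in the replaced segment, exactly and with 1 mismatch. That segment is the sequence taken out, so the result does not bear on Tetarr-ade6.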

Other observations

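Both tests in this part were chosen after the results they bear on had been seen, and neither concerns a difference between samples. No biological explanation was tested.

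The 3 gene records under a separate sequence name, mat2-Pc, 9xtetoura4 and mat3, may use positions of the edited chromosome II. If so, mat3 would stand at the RefSeq position of mat3-Mc plus the chromosome II offset. The start of mat3 minus that of mat3-Mc is 6539 bp, equal to the offset, the ends differ by the same amount, and all 3 records fall within the empty interval. The strand stays open: mat3 is written on the minus strand and mat3-Mc in RefSeq is on the plus strand. Under this hypothesis, a display or count restricted to chromosome II would show no 9xtetoura4 record, although bases of the reporter would lie there. With that placement, 13 genes of chromosome II within 20 kb of 9xtetoura4 are absent from the tetarr6 annotation, 0 of them protein-coding. Over the whole all-chromosomes annotation 5854 of 12633 genes are absent from it. The sequence itself was not used here.

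The missing ade6 record in the tetarr6 annotation may reflect sequence removed from chromosome III, rather than a record left out. Between bub1 and vtc4 the offset changes by -1828 bp, a larger change than the 1755 bp of ade6, as a removal requires and a lost record alone does not. The 541 bp left between these genes cannot hold ade6, which argues against a record left out alone. Unlike the replacement at ura4, this change has no editing record. Tetarr-ade6 is 1314 bp longer than ade6 in RefSeq, but whether it holds the whole gene was not tested.

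Positions from the 2 annotations cannot be pooled on chromosomes II and III without regard to the offsets. Of the 50 listed genes in both annotations, 20 lie in a shifted block, among them set1, chp2, ago1, dcr1 and epe1. In the all-chromosomes annotation 7196 non-coding transcripts carry coding sequence records, so a count over coding sequence records there includes non-coding genes.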
